A study of Mus musculus with 6 samples.

How the data were processed

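Total RNA from mouse kidney was sequenced in 6 libraries, 3 labelled WT and 3 labelled fat-1 knockin (fat-1 here), all at 24 months of age. The authors' deposited tables give FPKM (fragments per kilobase of transcript, scaled to the fragments mapped in the library) per transcript, with 1 table per sample. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mm10 build were used by the authors; the tool that made the FPKM values is not given in the sources used here. The tables list 27486 transcripts, all protein-coding, and each reaches at least 0.5 FPKM in at least 1 library, so lower transcripts were not analysed here. Sums over the listed transcripts are therefore not full gene totals where minor transcripts fall below that level. FPKM also depends on how reads were divided between transcripts and between near-identical genes, and a few abundant genes can shift every other value in a library.

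Transcript values were summed per gene identifier, giving 13696 genes, of which 6837 had 1 transcript. In 4 tables, 21 gene symbols had been turned into dates, on 64 lines. They were restored from a table without a date on that line, or else from the transcript's name. A name table for the mouse held 13670 of the identifiers. Coordinates are those of the tables, on mm10. Transcript lengths came from GENCODE release M21, on the same build, for 95.1% of transcripts.

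Depth was examined in the low values. For 6088 genes with 1 transcript, FPKM times length clustered at a step between 68.9 and 83.0 per library. The step was searched from 50 to 100, a range narrowed after a wider first search. Between 17.2% and 23.4% of values up to 10 steps lay within 0.05 of a whole multiple, where evenly spread values give 10%. Because the step was fitted to these same values, the share by chance is above 10%. Whole reads could not be recovered, so the depth is unknown and no counting intervals are given. No pair of libraries shared identical gene values (0 genes), and correlations of log2 values were between 0.938 and 0.972 within groups and between 0.938 and 0.962 across groups, so all 6 were used as separate samples.

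The test planned before the data were examined assumed counts. Because the values are FPKM, the fallback planned with it was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and robust variance estimation, no covariates and no rescaling between libraries. Genes with at least 1 FPKM in at least 3 libraries were kept (11698). Filter and scaling were settled once the unit was known. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Differences are fat-1 minus WT on the log2(FPKM + 1) scale, which understates the change of low genes; FPKM values are means ± SD over 3 libraries. Feeding, time of collection, sex and batch were not in the labels used here.

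Gene lists for pathways and cell types, 50 in all, were fixed before the data were examined. The 42 with at least 5 tested members entered camera with a preset correlation of 0.01. Beside it, camera with an estimated correlation and the directional fry test were run. All were adjusted over these lists. The other 8 were not tested in the main fit, though some entered fits with other filters. With 4 residual degrees of freedom the estimated correlation is imprecise. Lists overlap, since genes such as Col1a1, Plin2 and Slc22a8 belong to more than 1, and members of marker lists can be expressed by other kidney cells.

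Genes were named by a rule fixed in advance: up to 14 in each direction with an adjusted p under 0.05, a mean of at least 1 FPKM (CPM in the rule as written) and groups that did not overlap, ranked by log2 difference; up to 4 members with the smallest p in each list described; and a fixed set of fatty acid, metabolic, aging, injury and sex genes. Of that set, Cdkn2a and Xist were not analysed here. Some genes that the rule names are not reported here.

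Alternatives covered scaling, filters, pseudocount, robust estimation, each replicate left out, and the list tests. On data simulated for this comparison (11698 genes, 200 changed in each of 3 runs), the fit recovered 57.2% of genes changed 2-fold, 88.6% of those changed 4-fold and 98.0% of those changed 16-fold, 4.32% of calls were false, and 0 genes were called when nothing changed. Changed genes were drawn only from the more expressed ones, so the recovery does not cover low genes such as Prima1. Noise was independent between genes, so differences that many genes share between libraries were not simulated. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for joins and plots.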

Results

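Kidney transcriptomes of 24-month-old mice were compared between 3 wild-type (WT) samples and 3 samples labelled as a knockin of fat-1, a nematode gene for a desaturase that turns omega-6 into omega-3 polyunsaturated fatty acids. The comparison asks what this inserted gene changes in the aged kidney. The deposited tables gave FPKM per transcript, which were summed to 13696 protein-coding genes, and 11698 of these with at least 1 FPKM in at least 3 libraries were tested. Summed FPKM ranged from 387488 in fat-1 replicate 3 to 431081 in WT replicate 3, and mitochondrially encoded genes took between 12.1% and 16.7% of it. Read counts were not used here and the depth is unknown. The labels do not say whether the kidneys came from separate animals, so p-values measure the spread between these samples only. The inserted gene itself was not analysed here, so the genotype labels were not checked against it; mouse Fat1, a cadherin gene, is unrelated. Ddx3y, a Y-linked gene, was measured in both groups, at 11.6 ± 2.87 FPKM (SD, n = 3) in WT and 13.4 ± 2.06 FPKM (SD, n = 3) in fat-1. It was at 8.70 FPKM or more in every library, so Y-linked RNA was present in all 6.

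Pck1, Pdk4 and Slc25a25 were among the genes that rose in fat-1 kidneys. Pck1, the cytosolic entry enzyme of gluconeogenesis (chromosome 2, 173153048 to 173159273, mm10), rose from 242 ± 61.5 FPKM in WT to 1713 ± 169 FPKM in fat-1 (SD, n = 3 each), a log2 difference of 2.84 ± 0.20 (SE). Pdk4, a kinase that switches off pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose from 7.29 ± 0.433 to 53.8 ± 15.7 FPKM. Slc25a25, a mitochondrial carrier of ATP-magnesium and phosphate (chromosome 2, 32414487 to 32451445), rose from 12.7 ± 4.78 to 111 ± 32.9 FPKM. The adjusted p in limma was 0.0284 for Pck1 and Pdk4 and 0.0473 for Slc25a25.

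Altogether 21 genes passed an adjusted p of 0.05 in limma, 14 higher and 7 lower in fat-1, and in all 21 every fat-1 library lay on the same side of every WT library. Chance gives that arrangement for 10% of genes, and 15.2% of the tested genes showed it. The test favours genes with separated groups, so for the 21 genes the arrangement adds no separate support. Among transporters and metabolic enzymes, the glutamine transporter Slc38a3 rose from 7.49 ± 1.58 to 52.2 ± 21.8 FPKM, and the acyltransferase gene Mogat2 from 2.40 ± 1.25 to 18.4 ± 4.90 FPKM (SD, n = 3). Gldc of glycine cleavage rose by a log2 difference of 1.75 ± 0.20 (SE) and the pyruvate kinase gene Pklr by 1.46 ± 0.15. The chemokine gene Cxcl12 rose by 1.25 ± 0.14 on the same scale, Plvap of the endothelial fenestral diaphragm by 1.25 ± 0.15 and Egln3, a prolyl hydroxylase acting on hypoxia-inducible factors, by 1.25 ± 0.14. The collagen gene Col27a1 rose by 1.77 ± 0.22, the RNA-binding protein gene Cpeb3 by 1.49 ± 0.16 and Prima1, the membrane anchor of acetylcholinesterase, by 1.91 ± 0.23, the last from 0.151 ± 0.262 FPKM in WT. With a pseudocount of 0.1 the difference of Prima1 was 4.24 and its call was lost (adjusted p = 0.106).

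The genes that fell encoded proteins of varied kinds. Trmt1l, related to transfer RNA methyltransferases (chromosome 1, 151428542 to 151458161), fell from 7.13 ± 0.880 to 0.745 ± 0.255 FPKM (SD, n = 3), a log2 difference of -2.22 ± 0.18 (SE). Palm3, of the paralemmin family (chromosome 8, 84021471 to 84030295), fell from 14.5 ± 2.93 to 3.54 ± 0.318 FPKM. Rnf183 and Rnf181, both of the RING finger family, differed by -1.26 ± 0.11 and -1.32 ± 0.16, and the adhesion receptor gene Adgrg4 by -1.31 ± 0.15. Tmem254b fell from 86.0 ± 7.65 to 42.6 ± 1.90 FPKM and Tmem254c from 72.7 ± 4.90 to 38.5 ± 1.75 FPKM, but these chromosome 14 genes are near-identical copies whose reads may be split between them, so their separate values are uncertain.

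**Figure D1:**
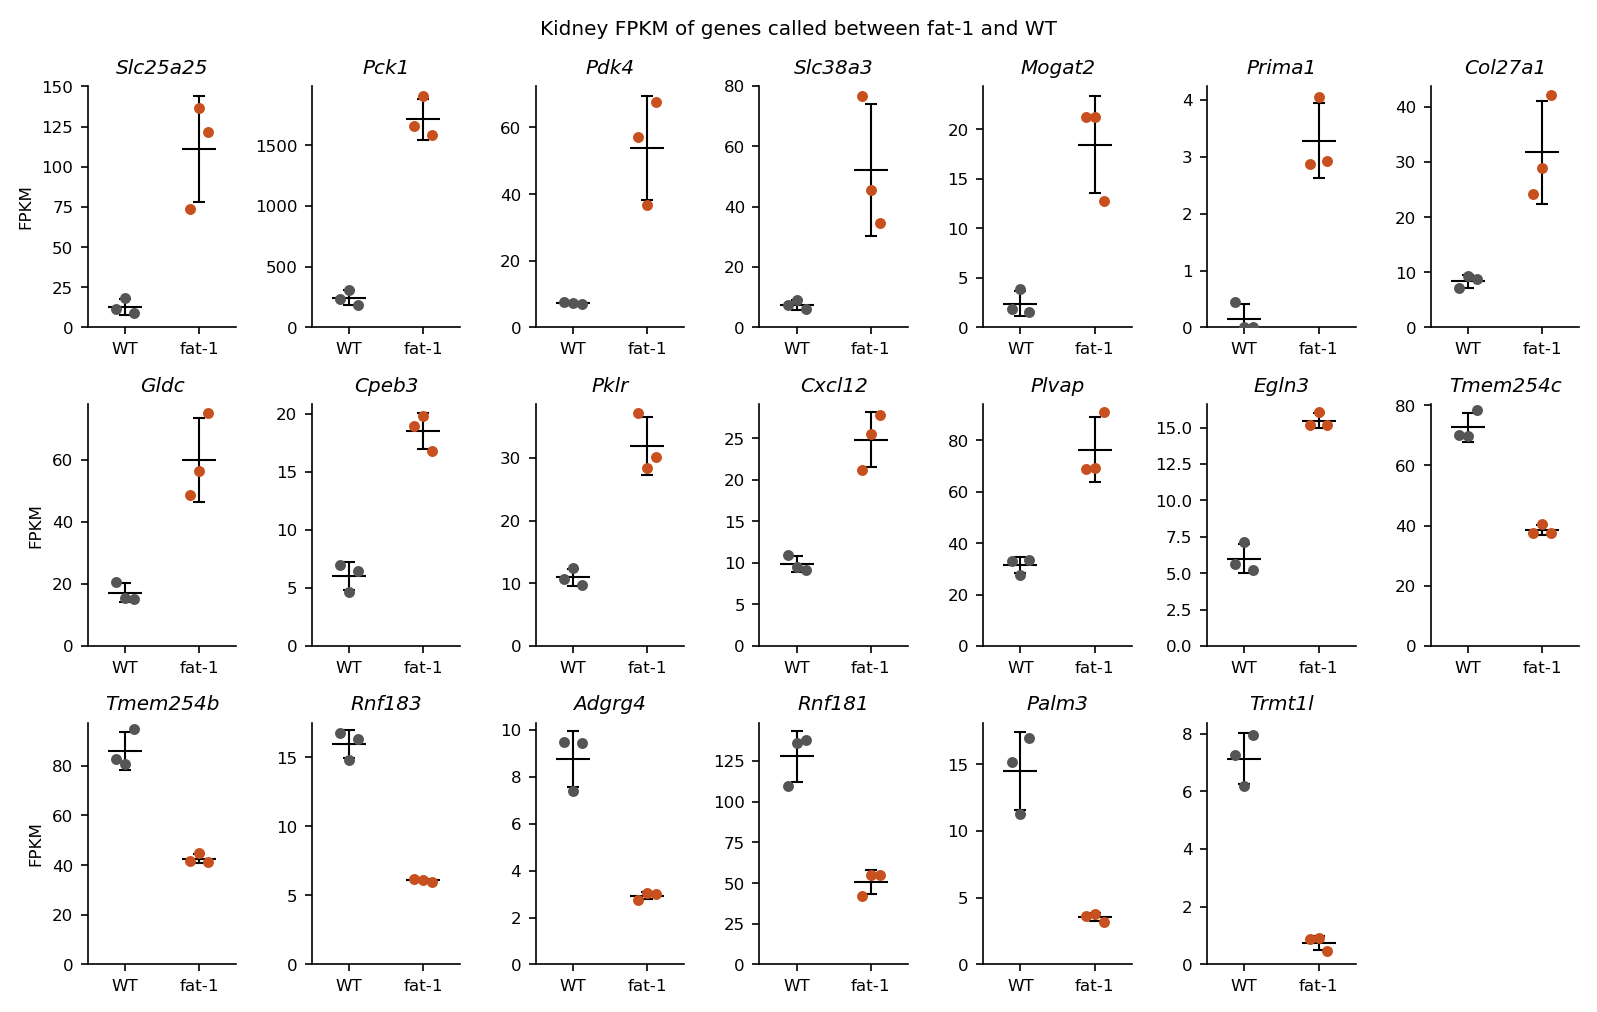
FPKM in each kidney library, with WT in grey and fat-1 in orange, for 20 of the 21 genes that passed the test, in order of log2 difference; bars give the mean and SD of 3 libraries, and each axis starts at 0. In every panel the 3 fat-1 libraries lie wholly above or wholly below the 3 WT libraries.

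The 21 calls lay close to the threshold, with adjusted p between 0.0284 and 0.0496, and their number changed with the library left out. Without WT replicate 3, fat-1 replicate 1 or fat-1 replicate 3, limma called 0 genes, against 831, 1005 and 1059 at an unadjusted p under 0.05; without WT replicate 2 it called Pck1 alone, without fat-1 replicate 2 Pdk4 alone, and without WT replicate 1 it called 25 genes, 9 of them shared. Under other scalings the count lay between 8 and 39, and with median-of-ratios factors 4 genes were higher and 4 lower; directions held for all 21 genes under every scaling tried. Over the alternatives tried the log2 difference of Pck1 lay between 2.67 and 3.03 and that of Rnf183 between -1.37 and -1.21, with or without a call.

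Genes of fatty acid use were higher together. Of 29 tested peroxisomal and PPAR alpha target genes, a set driven by a fatty acid-sensing nuclear receptor, 28 had a positive difference, with a median of 1.07. Over all genes 2 passed, Pdk4 among them, and 23 rose and 0 fell when adjusted over the list alone, among them the fatty acid hydroxylase gene Cyp4a10 at 160 ± 36.1 against 686 ± 187 FPKM and the lipid droplet coat gene Plin2 at 41.4 ± 3.40 against 112 ± 27.7 FPKM (SD, n = 3). Cyp4a10 has close paralogs, so its value is uncertain. The list was called higher by camera with a preset correlation (adjusted p = 2.98e-26) but not with an estimated correlation (adjusted p = 0.251 with an estimated correlation); fry gave an adjusted p of 0.0433. Ppara itself measured 5.77 ± 2.66 FPKM in WT and 15.6 ± 6.55 FPKM in fat-1 (adjusted p = 0.314).

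In the mitochondrial fatty acid oxidation list, 21 of 22 genes had a positive difference (median 0.60), 0 passed over all genes, and 15 rose and 0 fell when adjusted over the list alone. The thioesterase gene Acot2, a member of a paralog cluster, rose by 1.44 ± 0.20 (SE), the carnitine carrier gene Slc25a20 by 1.07 ± 0.18, Eci1 by 1.33 ± 0.23 and Decr1 by 1.07 ± 0.19 on the log2 scale, each by that adjustment. This list was called higher by camera with the preset correlation (adjusted p = 1.50e-15). The call was lost with an estimated one (adjusted p = 0.251 with an estimated correlation) and with fry (adjusted p = 0.053). Cpt1a, which admits fatty acids to mitochondria, measured 99.2 ± 17.3 FPKM in WT and 151 ± 21.7 FPKM in fat-1 (SD, n = 3; adjusted p = 0.260).

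With all 6 libraries, genes of the respiratory chain and the TCA cycle were not called as lists. The median log2 difference was -0.08 over 36 nuclear-encoded complex I genes (camera adjusted p = 0.159), -0.09 over 39 genes of complexes II to V (adjusted p = 0.103) and -0.08 over 13 mitochondrially encoded genes (adjusted p = 0.388), with 0 members of these lists called. Single libraries changed this. Camera with the preset correlation called complex I genes lower without WT replicate 1 (median -0.18, adjusted p = 2.41e-05) or fat-1 replicate 1 (-0.19, adjusted p = 0.000852). Their median was 0.06 without WT replicate 3. Complexes II to V were called lower without WT replicate 1 (median -0.21, adjusted p = 1.19e-05), fat-1 replicate 1 (-0.17, adjusted p = 0.00244) or fat-1 replicate 2 (-0.08, adjusted p = 0.0330). Mitochondrially encoded genes were called lower without WT replicate 1 (-0.25, adjusted p = 0.00115) or fat-1 replicate 2 (-0.19, adjusted p = 0.0371). Without both WT replicate 1 and fat-1 replicate 3, complex I genes (adjusted p = 0.0234) and complexes II to V (adjusted p = 0.0109) were called lower. In the TCA cycle and pyruvate entry list (median 0.01 over 25 genes, adjusted p = 0.330), Pcx, pyruvate carboxylase, rose from 103 ± 16.1 to 201 ± 23.1 FPKM (SD, n = 3) when adjusted over the list alone (adjusted p = 0.0130), as 1 of 25 members. This list was called higher without WT replicate 2 (median 0.05, adjusted p = 0.0464), WT replicate 3 (0.07, adjusted p = 0.0490) or fat-1 replicate 3 (0.08, adjusted p = 0.0439). The coactivator gene Ppargc1a differed by -0.08 ± 0.17 (SE; adjusted p = 0.954), and the list of mitochondrial biogenesis and energy sensing regulators was not called (median 0.09 over 24 genes, adjusted p = 0.159) except without WT replicate 2, where it was higher (median 0.11, adjusted p = 0.0464). In the glycolysis and gluconeogenesis list, Pck1 passed over all genes, and Pck1 and Eno1 rose among 21 members when adjusted over the list alone (list adjusted p = 0.159).

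Cholesterol synthesis genes were lower. In the list of cholesterol synthesis and SREBP targets, 22 of 27 genes had a negative difference (median -0.40), 0 passed over all genes, and 4 fell and 0 rose when adjusted over the list alone. Among them were Idi1, at 33.2 ± 7.82 against 9.65 ± 3.81 FPKM (SD, n = 3), Insig1 and Dhcr7. The list was called lower by camera with the preset correlation (adjusted p = 1.33e-06). The call was lost with an estimated one (adjusted p = 0.251 with an estimated correlation) and with fry (adjusted p = 0.132). The mouse desaturase genes for polyunsaturated fatty acids did not pass the test: Fads1 differed by -0.36 ± 0.17 (SE; adjusted p = 0.594) and Fads2 by -0.22 ± 0.20 (adjusted p = 0.836), while the elongase gene Elovl2 differed by 0.66 ± 0.44 (adjusted p = 0.747) and Elovl5 by 0.08 ± 0.19 (adjusted p = 0.964). In the 20-gene list of polyunsaturated fatty acid synthesis and handling (adjusted p = 0.330), the lipid chaperone gene Fabp4 rose, with a 95% interval of the log2 difference from 0.71 to 1.70, and the desaturase gene Scd2 fell by 0.89 on the log2 scale when adjusted over the list alone. Hpgd, which inactivates prostaglandins, rose in the same sense as 1 of 28 eicosanoid genes (1.18 ± 0.23; list adjusted p = 0.388).

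Lists of stress responses were called with smaller medians. Genes of endoplasmic reticulum stress and chaperones had a median of -0.21, and 3 of 22 fell and 0 rose when adjusted over the list alone, namely Sdf2l1, Pdia6 and Dnajb11 (list adjusted p = 0.00158; adjusted p = 0.632 with an estimated correlation). That median was -0.0991 without fat-1 replicate 1, -0.13 with no filter and -0.31 without both WT replicate 1 and fat-1 replicate 3. Among 28 NRF2 targets and antioxidant enzymes the median was 0.18; 2 rose when adjusted over the list alone, the glutathione transferase gene Gsta1, which has close paralogs, and the peroxiredoxin gene Prdx6 (list adjusted p = 0.00993; adjusted p = 0.784 with an estimated correlation). The NRF2 call was lost without WT replicate 1 (adjusted p = 0.0977) and without fat-1 replicate 1 (median 0.0805, adjusted p = 0.346). Heat shock genes were not called with all 6 libraries (median -0.13 over 18 genes, adjusted p = 0.0527). They were called lower without WT replicate 1 (-0.16, adjusted p = 3.66e-05), without fat-1 replicate 3 (-0.25, adjusted p = 0.00235), and without both (-0.39, adjusted p = 1.34e-06). The same held with no filter (adjusted p = 0.0472) and with a pseudocount of 0.1 (adjusted p = 0.0443). Immediate early genes had a median of 0.31 (adjusted p = 0.0647). They were called higher without WT replicate 1 (0.69, adjusted p = 1.77e-09) and without both of these libraries (0.62, adjusted p = 8.02e-09). They were also called higher with a pseudocount of 0.1 (adjusted p = 0.0443) and under 4 of 5 other scalings (adjusted p between 0.0232 and 0.0492). Their median was -0.04 without WT replicate 2.

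Markers of cell types differed in opposite directions. All 12 endothelial markers rose when adjusted over the list alone, with a median of 0.92: Plvap from 31.4 ± 3.23 to 76.5 ± 12.6 FPKM, Tek from 4.33 ± 0.537 to 12.6 ± 2.95 FPKM, Pecam1 from 9.55 ± 1.26 to 18.9 ± 3.40 FPKM and Emcn from 14.9 ± 1.97 to 30.3 ± 6.96 FPKM (SD, n = 3). Plvap alone of these passed over all genes; the list had an adjusted p of 2.72e-14 (adjusted p = 0.251 with an estimated correlation). Podocyte markers had a median of 0.44, and 3 of 9 rose when adjusted over the list alone, Podxl and Nphs1 among them (list adjusted p = 0.000277; adjusted p = 0.251 with an estimated correlation). Markers of intercalated cells, the acid-base regulating cells of the collecting duct, had a median of -0.41, and 6 of 12 fell by that adjustment, among them Slc26a4, at 27.5 ± 0.456 against 15.3 ± 3.40 FPKM, and the proton pump subunit genes Atp6v1g3 and Atp6v0d2. Their list adjusted p was 7.21e-07 (adjusted p = 0.198 with an estimated correlation; fry adjusted p 0.0344). Distal convoluted tubule markers had a median of -0.42, and 1 of 10 fell by that adjustment, Calb1, at 124 ± 28.3 against 37.0 ± 12.0 FPKM (list adjusted p = 2.19e-06; adjusted p = 0.603 with an estimated correlation). That median was -0.67 without WT replicate 3 and -0.25 without both WT replicate 1 and fat-1 replicate 3. Fry did not call the endothelial and podocyte lists (adjusted p = 0.0513 for each) or the distal convoluted tubule list (adjusted p = 0.21).

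Proximal tubule S1 and S2 markers were not called (median -0.06 over 12 genes, adjusted p = 0.778), although the organic anion transporter gene Slc22a8 and the dicarboxylate transporter gene Slc13a3 rose when adjusted over the list alone. With all 6 libraries, other marker lists were not called, including S3 proximal tubule (median -0.71, adjusted p = 0.189), thick ascending limb (-0.13, adjusted p = 0.330), principal cells (-0.24, adjusted p = 0.108), fibroblasts and pericytes (-0.19, adjusted p = 0.430), smooth muscle (0.05, adjusted p = 0.830), macrophages (-0.23, adjusted p = 0.330) and erythrocytes (-1.55, adjusted p = 0.116). Macrophage markers were called higher without WT replicate 1 (median 0.42, adjusted p = 0.00260) and without both WT replicate 1 and fat-1 replicate 3 (0.35, adjusted p = 0.0496). They were called lower without WT replicate 2 (-0.63, adjusted p = 0.0211) or WT replicate 3 (-0.55, adjusted p = 0.0365). Erythrocyte markers were called lower without fat-1 replicate 1 (-3.15, adjusted p = 6.19e-08), and their median was -0.46 without fat-1 replicate 3. S3 markers were called lower without WT replicate 1 (-0.93, adjusted p = 0.00874), fat-1 replicate 3 (-0.85, adjusted p = 0.0175) or both (-1.07, adjusted p = 0.000158). Without WT replicate 2 the S3 median was -0.35 (camera adjusted p = 0.726). Without fat-1 replicate 3, or without both, thick ascending limb (-0.44, adjusted p = 0.00102; -0.40, adjusted p = 0.00546) and principal cell markers (-0.40, adjusted p = 0.000688; -0.31, adjusted p = 0.0033) were called lower. Principal cell markers were also called lower with the trimmed mean of M values (adjusted p = 0.0484). Both lists varied within fat-1, relative to the mean of all 6 libraries. Replicate 2 lay lowest (-0.57 for thick ascending limb, -0.43 for principal cells) and replicate 3 highest (0.47 and 0.38). Male-biased kidney genes had a median of -0.33 with 0 of 21 called by either adjustment (list adjusted p = 0.00580; adjusted p = 0.828 with an estimated correlation), and this call was lost without WT replicate 2 (median -0.15, adjusted p = 0.142) and without WT replicate 3 (median -0.12, adjusted p = 0.104). The median was -0.75 without WT replicate 1, -0.56 without fat-1 replicate 2 and -0.58 without both WT replicate 1 and fat-1 replicate 3. Across the 42 lists tested, 11 were called with the preset correlation, 4 of them cell type lists, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. Each division of the same 6 libraries into mixed groups of 3 also called between 9 and 24 lists.

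**Figure D2:**
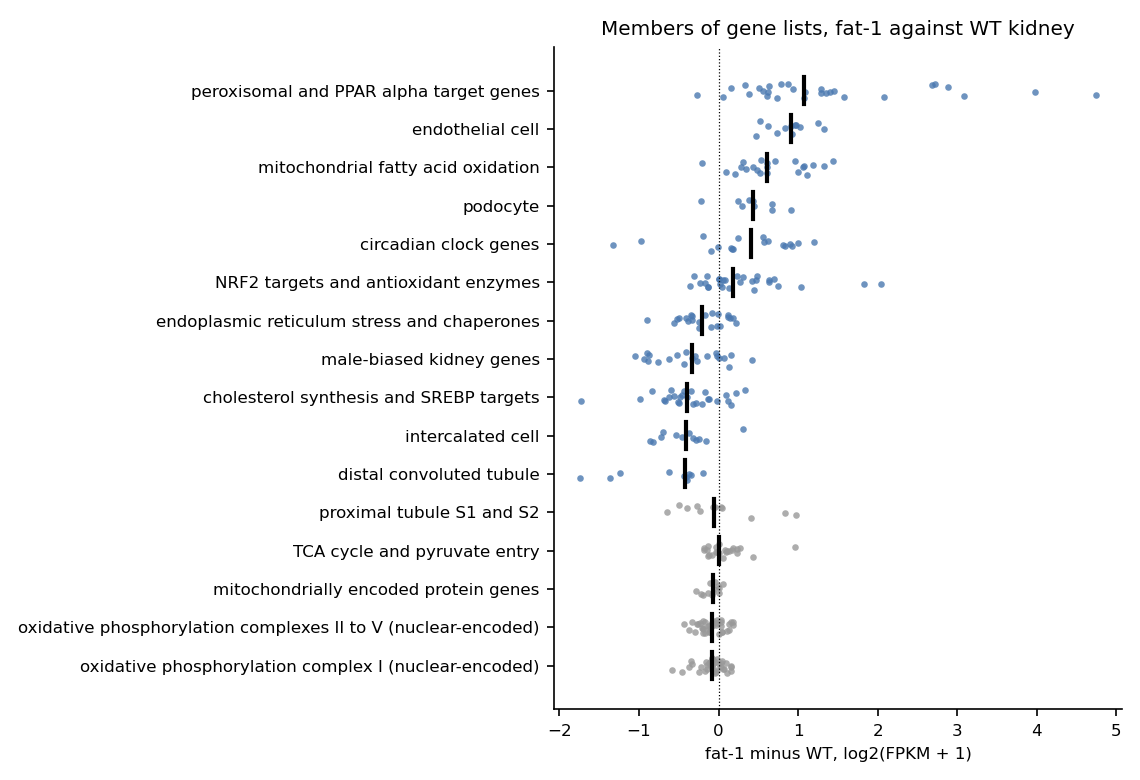
Difference between fat-1 and WT in log2(FPKM + 1) for each tested member (points) of the 11 lists called with the preset correlation (blue) and of 5 energy and proximal tubule lists that were not called (grey); black bars mark medians and vertical scatter is for display. The PPAR alpha target list has a median of 1.07 and the respiratory chain lists lie near 0.

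Circadian clock genes moved in both directions. Adjusted over the list alone, 5 of 18 rose and 2 fell, with 0 passing over all genes. The activator genes Arntl and Npas2 fell, from 5.30 ± 1.15 to 2.20 ± 0.492 FPKM and from 3.17 ± 0.637 to 0.662 ± 0.296 FPKM (SD, n = 3). The output gene Dbp rose from 13.6 ± 4.14 to 31.9 ± 5.35 FPKM and the period gene Per3 from 3.48 ± 0.877 to 7.07 ± 1.93 FPKM. As a list they had a median of 0.40 (adjusted p = 0.0305; adjusted p = 0.632 with an estimated correlation). The list call was lost without WT replicate 1 (adjusted p = 0.0537), WT replicate 3 (adjusted p = 0.0811) or fat-1 replicate 2 (adjusted p = 0.137), without both WT replicate 1 and fat-1 replicate 3 (median 0.25, adjusted p = 0.0763), and when scaled without mitochondrial and the 50 most abundant genes (adjusted p = 0.0598). The median was 0.20 without fat-1 replicate 3, 0.62 without fat-1 replicate 1 and 0.25 with no filter.

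**Figure D3:**
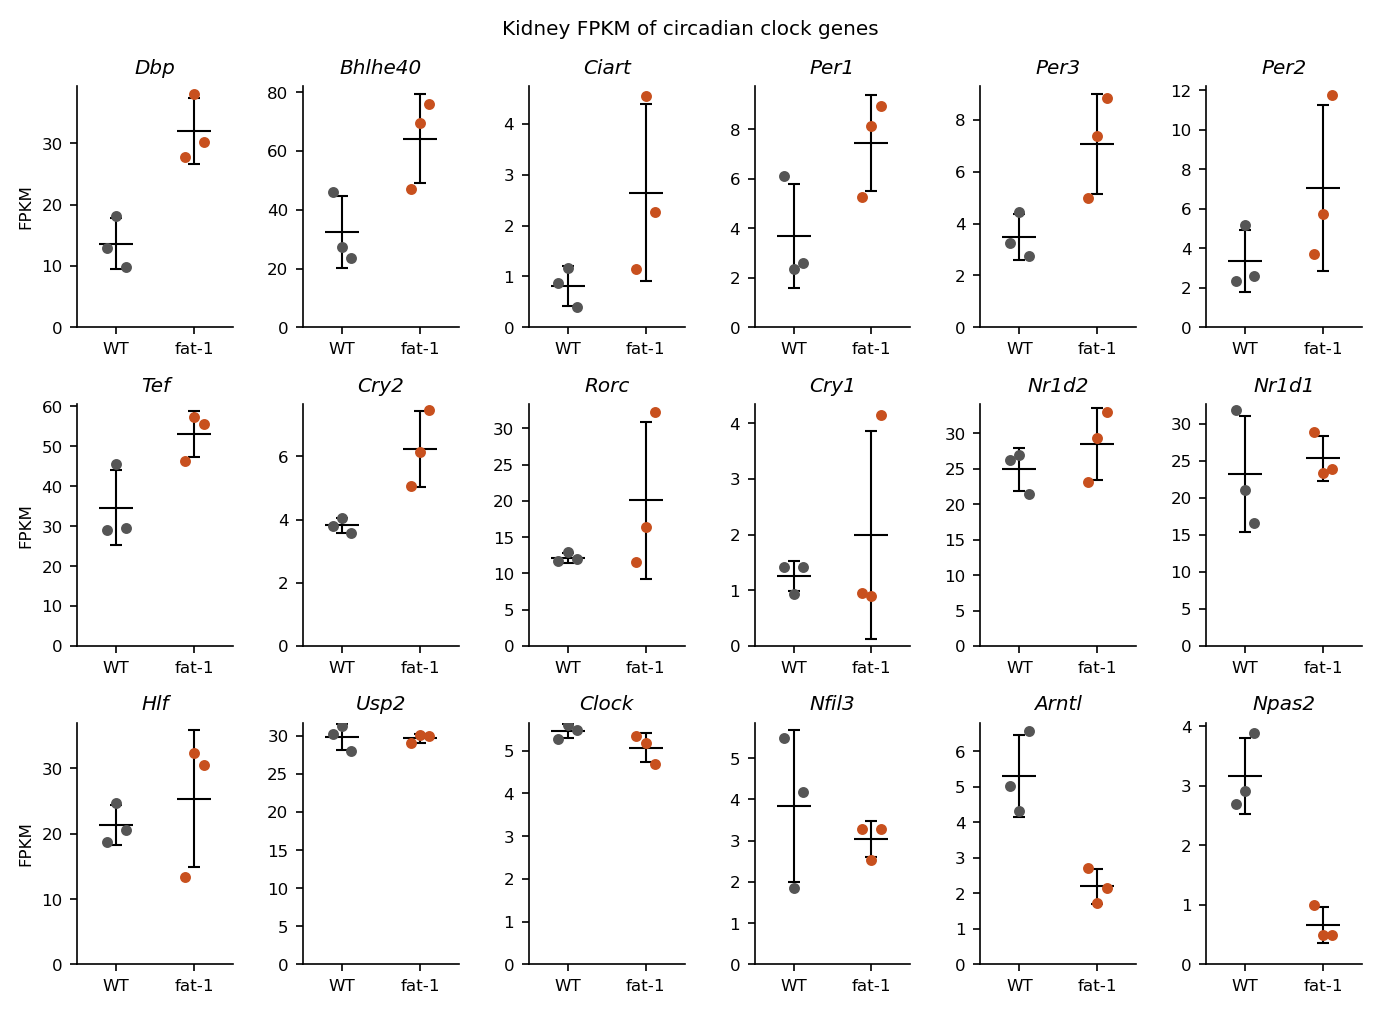
FPKM in each kidney library for the 18 tested circadian clock genes, in order of log2 difference, with WT in grey and fat-1 in orange; bars give the mean and SD of 3 libraries, and each axis starts at 0. Dbp lies higher and Arntl and Npas2 lie lower in all 3 fat-1 libraries.

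With all 6 libraries, genes tied to renal aging, inflammation and fibrosis gave no list calls. Kl, the klotho gene, measured 156 ± 8.17 FPKM in WT and 91.9 ± 23.4 FPKM in fat-1 (SD, n = 3), a log2 difference of -0.79 with a 95% interval from -1.25 to -0.33, and did not pass (adjusted p = 0.196 over all genes and 0.0733 over the list of 15 anti-aging and renal hormone genes alone). The senescence list had a median of 0.02 over 22 genes (adjusted p = 0.618) and of 0.21 without WT replicate 1 (adjusted p = 0.0955). The cell cycle inhibitor gene Cdkn1a measured 9.79 ± 4.94 and 8.81 ± 3.78 FPKM (adjusted p = 0.980). Injury markers varied between libraries: Havcr1 measured 18.2 ± 4.94 FPKM in WT and 28.5 ± 34.3 FPKM in fat-1, and Lcn2 measured 27.1 ± 29.5 and 43.9 ± 34.3 FPKM. Their list had a median of 0.03 (adjusted p = 0.330) and was called higher without WT replicate 1 (0.53, adjusted p = 0.00917) or fat-1 replicate 2 (0.45, adjusted p = 0.000296). In the extracellular matrix list (median -0.05 over 34 genes, adjusted p = 0.436), Col1a1 measured 6.91 ± 1.13 and 3.84 ± 1.23 FPKM (adjusted p = 0.321). The list was called lower without WT replicate 2 (-0.18, adjusted p = 0.0173) and had a median of 0.19 without WT replicate 1 (adjusted p = 0.400). The inflammation list had a median of -0.04 over 24 genes (adjusted p = 0.723), with Cxcl12 its only member called. It was called higher without WT replicate 1 (0.41, adjusted p = 8.14e-05) and without both WT replicate 1 and fat-1 replicate 3 (0.32, adjusted p = 0.000256). Il6 was listed at 0 in 4 of 6 libraries, and Tnf was at 3.20 FPKM in WT replicate 1 and at most 0.397 FPKM in the other libraries.

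WT replicate 1 stood apart from the other WT libraries in immune genes. Its mean over interferon-stimulated genes lay 2.21 log2 units above the mean of all 6 libraries, against -0.82 and -0.84 in WT replicates 2 and 3, and its mean over MHC class II genes lay 2.38 above. Neither list was called with all 6 libraries (medians -0.33 and -0.40, adjusted p = 0.330 and 0.511). Interferon-stimulated genes were called higher in fat-1 without WT replicate 1 (0.59, adjusted p = 1.06e-08). They were called lower without WT replicate 2 (-0.69, adjusted p = 0.00701) or WT replicate 3 (-0.80, adjusted p = 0.00302). MHC class II genes were called higher without WT replicate 1 (0.73, adjusted p = 0.00480). Immune cell markers of WT replicate 1 also lay above the mean of all 6 libraries. They lay 1.96 log2 units above it for T and NK cells, 1.56 for macrophages and monocytes and 1.46 for B and plasma cells. Without WT replicate 2, camera called the T and NK list (median -1.16, adjusted p = 0.0115) and the B cell list (-0.71, adjusted p = 0.0235) lower. On the first principal component, which held 34.2% of the variance, WT replicate 1 scored -41.1 and fat-1 replicate 3 scored -15.1, while the other 4 libraries scored between 3.73 and 24.7. On the second component, with 26.2%, WT libraries scored between -23.4 and -11.2 and fat-1 libraries between 15.0 and 21.2. WT replicate 1 and fat-1 replicate 3 also had the lowest mitochondrial shares, 12.1% and 12.6% against 13.8% to 16.7% in the other libraries. Their median gene FPKM was highest, at 7.15 and 7.06 against 6.01 to 6.33. What the first component reflects was not tested. With both of these libraries left out, an alternative chosen after seeing the data, limma called 0 genes against 1389 at an unadjusted p under 0.05, and camera called 21 lists. Among these, interferon-stimulated (median 0.515, adjusted p = 1.04e-08) and MHC class II genes (0.39, adjusted p = 0.0033) were higher.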

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

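The trimmed mean of M values, quantile normalization, the test per transcript and the fit without both WT replicate 1 and fat-1 replicate 3 were chosen after seeing the data. The 21 genes changed (14 higher, 7 lower) became 8 with median-of-ratios factors (4 higher, 4 lower), 11 with upper-quartile factors, 4 with no filter (Pck1, Pdk4, Trmt1l and Rnf183), 38 when scaled without mitochondrial and the 50 most abundant genes, 8 with the trimmed mean of M values (4 higher, 4 lower), 39 with quantile normalization (19 shared), 10 for each transcript tested on its own and 0 with both libraries left out; the cause was not tested. Leaving out each replicate gave between 0 and 25 genes, where fewer libraries enter the fit. The 11 lists became 0 with an estimated correlation, 14 on gene ranks (with all 11 among them), 2 with fry (the PPAR alpha target and intercalated cell lists) and 21 with both libraries left out, and leaving out each replicate gave between 12 and 20. The 4 cell type lists became 0 with an estimated correlation, 1 with fry and 8 with both libraries left out, and leaving out each replicate gave between 4 and 7. With no filter they became 6. There camera with the preset correlation called adipocyte markers higher (median 0.32, adjusted p = 0.00698) and neutrophil markers lower (median -0.85, adjusted p = 0.0229). Neither list had enough tested members in the main fit. The 90 list members passing over their list alone numbered between 64 and 130 with each replicate left out, and 131 with both left out.

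Over these alternatives the 21 genes gave 328 tested values with 0 reversed. Of these values, 130 kept the call and 198 lost it. The groups did not overlap for these genes, so leaving out libraries or changing the pseudocount could not reverse a direction. Filters and robust estimation leave the difference itself unchanged. Only the other scalings could have reversed a direction. Trmt1l and Prima1 dropped below the filter in 4 of 16 fits. For the 11 lists, 167 of 176 camera calls with the preset correlation were kept. The 9 lost ones concerned clock, male-biased and NRF2 genes. Turning robust estimation off does not enter camera, so its 11 kept calls repeat the main result. Tests that need counts, DESeq2's Wald test and voom, were not run, since the deposited values are FPKM. No paired analysis was possible because the labels give no numbers shared by WT and fat-1 samples. The replicate numbers used here only follow the order of the samples. Unknown depth leaves the counting error of low genes such as Prima1 open.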

Other observations

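Tests chosen only after the result was seen were those on transcripts, on proximal tubule, tubule share and large vessels, on the clock genes, and the divisions of libraries for called genes and for the feeding, clock and endothelial sets; the genes named in these paragraphs were also chosen after their values were seen. Some single transcripts moved where the gene sum did not pass. Of 17119 transcripts tested with limma, 10 had an adjusted p under 0.05, and 2 of these, Pck1-201 and Pdk4-201, came from genes whose sum passed. Tkt-207, a transcript of transketolase, was at 24.2, 18.8 and 27.5 FPKM in the WT libraries and listed at 0 in all 3 fat-1 libraries (adjusted p = 0.00635), while Tkt as a whole measured 37.1 FPKM in WT and 27.1 FPKM in fat-1. Arhgap29-207 was listed at 0 in all 3 WT libraries and at 13.6, 14.7 and 10.8 FPKM in fat-1 (adjusted p = 0.00963). Ubtf-205 was at most 0.0189 FPKM in WT and at 8.22, 13.1 and 18.3 FPKM in fat-1, with Ubtf as a whole at 26.5 and 27.3 FPKM. In all, 6 transcripts were at 5 FPKM or more throughout 1 group and at 0.5 FPKM or less throughout the other, and another division of the libraries gave 10 such transcripts.

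The 10 divisions of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real division called 21 genes and the highest other 4, so 1 of 10 gave as many. For lists the real division called 11 and the highest other 24, and 9 of 10 called as many; for cell type lists these were 4 and 9, again with 9 of 10. List members adjusted over their list alone numbered 90 in the real division and 54 in the highest other, with 1 of 10 as large. The 4 divisions with WT replicate 1 and fat-1 replicate 3 on the same side called between 19 and 24 lists, which points to a structure of the samples across genotypes. For the PPAR alpha target list the adjusted p of 2.98e-26 was the lowest of the 10 divisions, the next being 4.00e-17, and 6 other called lists also had their lowest adjusted p in the real division. For the remaining called lists a mixed division went lower. It gave 5.78e-09 against 2.19e-06 for distal convoluted tubule markers, 0.00124 against 0.0305 for clock genes and 0.000173 against 0.00993 for NRF2 targets. Each of these had 3 of 10 divisions as low. For male-biased genes it was 2.85e-16 against 0.00580, with 5 of 10. The lists compared were those that the real division called, which favours it here. Mixed divisions also keep part of any genotype difference. Their lowest camera adjusted p was 6.49e-11 for fatty acid oxidation and 1.31e-09 for endothelial markers.

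The higher PPAR alpha target and fatty acid oxidation genes were weighed first. A larger share of proximal tubule in the fat-1 kidneys is argued against by a median of -0.0579 for S1 and S2 markers. Their mean lay 1.35 ± 0.265 below that of the target list (SE over genes, not kidneys). Scaling is argued against by a target list median that was 1.05 at its lowest over the scalings tried. Less recent feeding of the fat-1 mice may account for the pattern: 16 insulin- and FOXO-responsive genes outside the lists had a median of 0.24, above 99.98% of 10000 random lists, with 11 positive, but 5 were negative, among them Bcl6 (-0.81) and Klf15 (-0.56), and 3 of the 10 divisions gave a median as large, so feeding and genotype cannot be told apart here. Time of collection was not in the labels used here and was not weighed for these genes. An effect of the omega-3 fatty acids made by fat-1 on PPAR alpha stays open, untested.

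For the clock genes, collection at another time of day and an effect of genotype on the clock cannot be told apart. The 12 genes that peak with Dbp had a median of 0.72 and the 4 that peak with Arntl a median of -0.58, a gap of 1.30, and the widest gap in another division of the libraries was 1.15. These are the genes whose opposite movement prompted the comparison, so the gap supports neither explanation, and collection times were not in the labels used here.

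For the higher endothelial markers, a smaller share of tubule cells would raise the types outside the tubule alike, as for podocytes (median 0.44). Fibroblast and pericyte markers did not rise alike: their mean lay 1.02 ± 0.18 below the endothelial mean (SE over marker genes, not kidneys). That list was mixed, with 3 genes positive, Pdgfra (0.64) and Pdgfrb (0.40) among them, and 6 negative. Its median was 0.10 without WT replicate 1. Tubule lists had negative medians, from -0.06 for S1 and S2 to -0.71 for S3, so a smaller tubule share stays open. More large vessel wall is argued against by smooth muscle markers, whose mean lay 0.833 ± 0.118 below the endothelial mean (SE over marker genes). A larger share of endothelial cells may account for the pattern. A second set of 17 endothelial genes, written down before its values were seen, had a median of 0.64, with 16 positive. The largest median in another division was 0.518. In this set 9 did not overlap between groups, where chance gives 10% and 15.2% of all tested genes showed it. Such genes can move together, so the 9 are not separate pieces of support. An equal gain of all endothelial cells would raise them alike, but Cldn5 (0.09), Icam2 (0.12) and Ecscr (0.17) moved little and Sox17 was lower (-0.28). A gain of only some endothelial cells need not raise them alike, and this was not tested. Regulation within endothelial cells and an effect of genotype stay open, untested.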
